A study of Homo sapiens with 25 samples.

How the data were processed

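The data are ATAC-seq peak lists of B cell populations that were isolated by density gradient from human tonsil and sorted by surface markers, 1 list for each of 25 libraries. Per the labels, nuclei were treated with the Omni-ATAC protocol and libraries made with Nextera reagents. Bowtie2, Genrich and the build GRCh38 are named in the submitters' processing notes, without their roles, versions or settings, and whether reads were shifted for the transposase offset is not given in the sources used here. The deposited lists have 10 columns and no header. Their positions are interval starts, ends and summit offsets in base pairs, other values in the deposited lists being a score, a fold enrichment ratio and −log10 p and q values per peak. The score in the deposited lists is 10 times the −log10 p-value, cut to a whole number, in 99.9555 to 99.9991% of the entries of a library, and intervals with several summits are repeated, a layout that differs from the usual output of Genrich, so the caller is left open here. The fold enrichment ratio that the authors' caller gave was not used. The −log10 p as deposited served to rank peaks within a library and, for naive and memory B cells, to describe how strong the ranked peaks were. The smallest −log10 p was 3 in each list. Peaks were called by the authors separately in each library, since each sample has its own list, and no sign of pooling was seen. Each repeated interval was counted once, and chromosomes 1 to 22 and X were kept.

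Read counts per library were not used here, so neither depth nor the precision of a single peak is known. The depth is described by the number of peaks and the peak-covered length, and only the spread between libraries measures precision. Coordinates were set against the RefSeq gene table for GRCh38.p14, which gives gene positions without strand, and no genome sequence was used. Of the peaks of naive B cell replicate 1, 18.65% lay within 1 kb of the end of a coding gene, and 4.4% did so when the gene ends were moved by 1 Mb, as a check of the build.

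For each of 19974 protein-coding genes the locus was the gene body plus 10 kb on each side. The value of a locus in a library was its peak-covered length in ppm of the library's total peak-covered length. This value moves with how much was called in a library, and neighbouring loci can share a peak. Loci with a mean of at least 5 ppm were kept, which left 17711. log2(ppm + 5) was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a trend) in a single fit of the 6 groups, and p-values, two-sided, were adjusted by Benjamini-Hochberg over the 17711 loci with a threshold of 0.05. A log2 fold change on the log2(ppm + 5) scale understates the change of low loci. The comparisons were centroblasts, memory B cells, plasma cells and unsplit germinal centre B cells against naive B cells, and centrocytes against centroblasts. The number of libraries was 6, 2, 7, 3, 3 and 4 for naive B cells, unsplit germinal centre B cells, centroblasts, centrocytes, memory B cells and plasma cells. Groups were taken from the titles and marker labels. In their sample names 3 of the 7 centroblast libraries carry the abbreviation CB and 4 carry GCB, which the series design text uses for CXCR4+ centroblasts.

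Consensus regions were the merged intervals found in at least 2 libraries, and a library held a region if a peak overlapped it by at least 1 bp. For each region Fisher's exact test, two-sided, compared how many libraries of each of the 2 groups held it, with Benjamini-Hochberg adjustment. Tested were regions present in at least, and absent from at least, as many of the compared libraries as the smaller group holds. This filter on the margins also drops some regions whose totals allow an unadjusted p below 0.05. A region was called separated if each library of one group and none of the other held it. With fewer libraries this count can only stay or rise. The 4 main comparisons were tested in this way. Regions were assigned to the nearest coding gene.

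Before the data were examined 12 lists of 196 genes were fixed for naive and resting B cells, the germinal centre, the dark zone, the light zone and activation, memory B cells, plasma cells, B cell identity, T cells, natural killer cells, myeloid cells, stroma and epithelium, and housekeeping. They were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over 48 tests, and again with an estimated correlation, under which none of the 8 list calls held. The level of a list in a library is the mean log2(ppm + 5) of its genes minus that of all genes. Genes were named by a rule, also fixed before: for each comparison 12 anchors whatever their result, 11 of which are reported here (BCL6, MME, CXCR4, CD83, PRDM1, XBP1, IRF4, PAX5, CCR7, CD27 and S1PR2), the 8 largest rises and 8 largest falls that passed at loci that do not overlap, and the 2 genes of each list with the smallest adjusted p, or the 3 smallest unadjusted p in each direction where nothing passed. Not every gene that the rule selects, anchors included, is given below for every comparison. Genes outside the rule are said to be so where they are named. Peak numbers, covered lengths and peak widths were compared by exact permutation tests with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

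The gene-level test was checked on simulated data with 200 changed loci per comparison among 17711. It found 75% of loci changed by 1 on the log2 scale for centroblasts against naive B cells, 62% for centrocytes against centroblasts, 59% for memory B cells, 67% for plasma cells and 44% for unsplit cells against naive B cells. It found 97%, 91%, 95%, 93% and 90% of loci changed by 2, and false calls made up 3.91%, 3.17%, 5.52%, 6.98% and 7.59% of the calls. The simulated noise was independent between loci and held no effect of the covered length, so these shares need not hold in these data. The region test called 100% of simulated separated regions for centroblasts and plasma cells against naive B cells and 0% for the other 2 comparisons. In that simulation 6000 of 60000 regions were separated, and whether the smallest p passes depends on this share. The 100% and 0% thus do not measure power in these data.

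The alternatives were an equal number of 74353 strongest peaks per library, the 30000 strongest peaks, pseudocounts of 1 and 20 ppm, no filter on low values, scaling by the median ratio, the covered length or the style of the sample names as a covariate, the replicate number or the code shared by sample names as a block, a fit of only the 2 groups compared, fits within a name style, and leaving out each library in turn. For regions they were 50% coverage, presence in at least 4 libraries, both peak thresholds, no filter on the margins and limma on presence. Gene bodies without flanks or with 50 kb, the covered length with an equal number of peaks, the lists with the covered length, and fits without libraries of one shared name code or with only the 3 centroblast libraries named CB were added after seeing the data. Motif content, GC content and windows around transcription start sites were not analysed here, since they need sequence or strand.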

Results

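Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open chromatin, in B cell populations sorted from human tonsil, a lymphoid organ with active germinal centres. The 25 libraries fell into 6 groups by their surface markers. There were 6 libraries of naive B cells (IgD+), 7 of centroblasts (CXCR4+), 3 of centrocytes (CXCR4−), 3 of memory B cells (CD38− CD27+), 4 of plasma cells (CD38+ CD27+) and 2 of germinal centre B cells sorted without a CXCR4 gate, called unsplit here. Centroblasts are the dividing and mutating cells of the germinal centre dark zone, and centrocytes are the cells under selection in the light zone. Each library came as one list of peaks on GRCh38, and the number of reads behind each list was not given in the sources used here. The depth of a library is thus known only through what was called in it. The lists held between 74353 and 121949 distinct peaks. They covered 46.9, 31.1, 32.4, 30.4, 30.8 and 35.1 Mb in naive B cell replicates 1 to 6 and 25.8, 55.4, 54.0, 36.2, 34.5, 39.3 and 37.6 Mb in centroblast replicates 1 to 7. They covered 29.3, 58.4 and 50.6 Mb in centrocyte replicates 1 to 3, 23.3, 52.8 and 23.1 Mb in memory B cell replicates 1 to 3, 27.5, 21.3, 23.1 and 34.5 Mb in plasma cell replicates 1 to 4, and 35.5 and 39.5 Mb in the unsplit replicates 1 and 2. The peaks merged into 223183 consensus regions present in at least 2 libraries, of which 15135 were present in all 25.

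Naive B cells held 89468 ± 7597 peaks (SD, n = 6) and centroblasts 102350 ± 14557 (n = 7; exact permutation p = 0.0828). Centrocytes held 116450 ± 6302 peaks (n = 3; exact permutation p = 0.117 against centroblasts), memory B cells 97900 ± 8594 (n = 3; exact permutation p = 0.190 against naive B cells) and plasma cells 89774 ± 15609 (n = 4; exact permutation p = 0.981 against naive B cells). Plasma cells had narrower peaks than naive B cells (median width 226 ± 21.2 against 297.5 ± 53.5 bp; exact permutation p = 0.0286 before adjustment) and less covered length (26.6 ± 5.87 against 34.4 ± 6.32 Mb; exact permutation p = 0.0762). Over the 12 two-sided tests of peak number, covered length and median peak width the smallest adjusted p of these exact tests was 0.331, so none passed. Before adjustment the naive B cell against centroblast test of peak number fell below 0.05 without centroblast replicate 1 (exact permutation p = 0.0152) or without naive B cell replicate 4 (exact permutation p = 0.0480), and the centrocyte against centroblast test did so without centroblast replicate 7 (exact permutation p = 0.0476). All p-values here measure only the spread between these samples, since the labels do not say which libraries came from separate donors.

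The first principal component of the gene-level values held 27.6% of the variance and followed the covered length of the libraries (Pearson r = -0.793 with log2 length over the 25 libraries, described only). The second held 16.5% and placed the 6 naive B cell libraries, at 29.7 to 50.5, above the germinal centre libraries, at -33.1 to -8.59. Memory B cell replicates 1 and 3 lay at 74.2 and 59.9 on the first component and memory B cell replicate 2 lay at -45.3. The bases covered in both libraries of a pair, as a share of those covered in either, were 0.164 to 0.201 between memory B cell libraries. Between memory and naive B cell libraries the median was 0.244, with the highest, 0.710, for memory B cell replicate 2 and naive B cell replicate 1. The memory B cell libraries were thus not more alike to each other than to naive B cells.

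**Figure D1:**
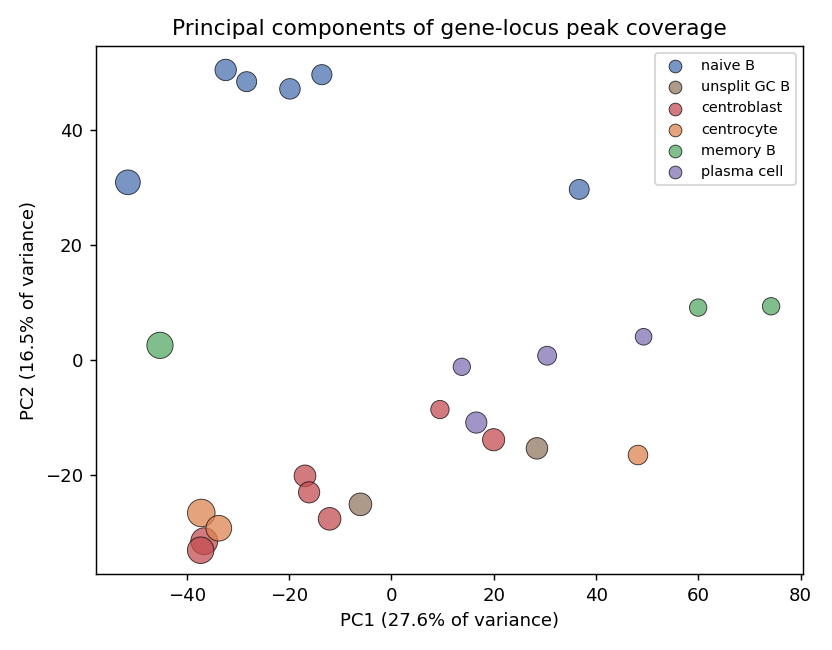
First and second principal components of log2 peak coverage over gene loci for the 25 libraries, with each point a library coloured by group and its area proportional to the covered length in Mb. The second component places naive B cells at 29.7 to 50.5 and the centroblast, centrocyte and unsplit libraries at or below -8.59, while the 3 memory B cell libraries lie at 74.2, 59.9 and -45.3 on the first.

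Centroblasts were compared with naive B cells to see which loci differ between resting cells and dividing germinal centre cells. SERPINA9, a serine protease inhibitor of germinal centre B cells, rose from 9.42 ± 12.1 ppm (SD, n = 6) to 84.1 ± 10.5 ppm (n = 7) of the covered length, a log2 fold change of 2.99 ± 0.34 (SE; adjusted p = 1.93e-06). RGS13, a regulator of G protein signalling, rose by 1.12 ± 0.17 (adjusted p = 0.000103). IL7R, the interleukin-7 receptor chain, fell by 2.47 ± 0.48 (adjusted p = 0.00106), and CD200, an inhibitory surface ligand, fell by 1.22 ± 0.19 (adjusted p = 9.26e-05).

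Of 17711 loci tested, 2207 passed in centroblasts against naive B cells, 1397 higher and 810 lower. Of the 21 genes of the germinal centre list, 6 rose and 0 fell, and 8 rose and 0 fell when adjusted over the list alone. The list as a whole was higher (camera adjusted p = 8.7e-05; adjusted p = 0.892 with an estimated correlation). Other genes of the germinal centre or its sort did not pass at the locus as a whole: BCL6, the transcriptional repressor of the germinal centre programme, stood at 0.18 ± 0.21, MME, which encodes the sorting marker CD10, at 0.02 ± 0.27, S1PR2, a confinement receptor, at 0.22 ± 0.14 and CXCR4, the sorting marker, at 0.23 ± 0.31. Of the 15 naive and resting B cell genes, 0 rose and 4 fell, and 5 fell when adjusted over the list alone (camera adjusted p = 1.85e-05; adjusted p = 0.892 with an estimated correlation). They included CD200 and the drug efflux pump gene ABCB1, which fell by 0.83 ± 0.16 (adjusted p = 0.00117). The homing receptor CCR7 stood at -0.69 ± 0.33 and did not pass (adjusted p = 0.191). Among 15 dark zone genes 2 rose and 0 fell, the proliferation marker MKI67 by 0.69 ± 0.16 (adjusted p = 0.0063) and the cell cycle factor E2F8 by 0.66 ± 0.20 (adjusted p = 0.0266), and the same 2 counts held when adjusted over the list alone (camera adjusted p = 0.165). Among 21 light zone and activation genes 0 rose and 1 fell, with 0 and 0 adjusted over the list alone. Among 16 memory genes 2 rose, the co-stimulatory CD80 by 0.61 ± 0.12 (adjusted p = 0.00179) and CD27 by 0.59 ± 0.16 (adjusted p = 0.0119), and 0 fell, with 2 and 1 adjusted over the list alone. Among 22 plasma cell genes 0 rose and 2 fell, also when adjusted over the list alone. These were CREB3L2, a transcription factor of the secretory pathway, by 1.22 ± 0.13 (adjusted p = 1.33e-06) and IRF4, a regulator of plasma cell differentiation, by 0.73 ± 0.18 (adjusted p = 0.00933). None of the 20 B cell identity genes passed by limma, over all genes or adjusted over the list alone.

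The largest rises lay at STXBP6 (4.12 ± 0.39), CADPS (3.98 ± 0.37), POTEA (3.51 ± 0.34), SCNN1B, an epithelial sodium channel subunit (3.48 ± 0.26), THSD4 (3.38 ± 0.34), BMP7, a secreted morphogen (3.23 ± 0.40), and the adhesion gene CADM1 (3.14 ± 0.26), with adjusted p between 1.22e-08 and 7.81e-06. The largest falls among named genes lay at SLC24A2 (-2.72 ± 0.45), ARPP21 (-2.64 ± 0.45), LUZP2 (-2.61 ± 0.71) and NETO1 (-2.61 ± 0.46). Markers of other cell types moved in both directions. Of 11 epithelial and stromal genes 3 rose and 0 fell (3 and 1 adjusted over the list alone), among them TP63, a basal epithelial factor, by 2.37 ± 0.37 (adjusted p = 0.000109). Of 13 myeloid genes 2 rose and 0 fell (5 and 1 adjusted over the list alone), of 8 natural killer cell genes 1 rose and 1 fell (3 and 2), and of 19 T cell genes 2 rose and 2 fell (2 and 2), the falls being IL7R and CD6. None of the 12 housekeeping genes passed by limma, over all genes or over the list alone. Adjusted p from camera lay between 0.165 and 0.995 for the 10 lists not called here.

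Single regions were compared by their presence. A Fisher's exact test of presence per library passed for 5080 of 15586 regions tested, 3564 present more often in centroblasts and 1516 in naive B cells. Of these, 1339 were present in all 7 centroblast libraries and in 0 of 6 naive B cell libraries, and 755 the reverse, for which chance gives an exact p of 0.000583 each. The excess towards centroblasts was not kept under all alternatives. With the 30000 strongest peaks 1779 regions were called towards centroblasts and 1889 towards naive B cells. Without naive B cell replicate 4 the counts were 1420 and 1718. These are not on the same footing, since fewer libraries change which regions Fisher's test can pass. Separated regions numbered 836 and 914 with the 30000 strongest peaks and 710 and 800 where 50% of the region had to be covered. CXCR4 was the nearest coding gene to 4 of the centroblast regions, among them one at chromosome 2, 136113334 to 136113985, 363 bp from the gene. BCL6 had 2, one at chromosome 3, 187719877 to 187720915, 461 bp from the gene, and one at 187932181 to 187933372, 186712 bp away towards LPP. Regions nearest to germinal centre genes were separated 14 times towards centroblasts and 0 times towards naive B cells (Fisher's exact adjusted p = 0.0263 against the 63.9% of all separated regions that lay towards centroblasts, a test added after the counts were seen). Regions near one gene are not independent of each other.

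The centroblast libraries all carried 1 style of sample name and the naive B cell libraries both. With the name style as a covariate 1555 loci passed, and within the 1 style that both groups share 1027 passed. The count rose to 3318 when the fit held only these 2 groups, and to 3383 with flanks of 50 kb, an alternative added after seeing the data. The region count fell to between 2172 and 3138 without any 1 library other than centroblast replicate 1, without which it was 3696. Separated regions had the same range without 1 library, 2172 to 3696, and numbered 2094 with all. The fall thus need not mean that 1 library carries these regions, since fewer libraries leave Fisher's test fewer steps. The count was 0 with no filter on the margins, where every region held by any of these libraries shares the adjustment. SERPINA9, RGS13, ABCB1, CREB3L2, CADPS, SCNN1B and CADM1 were among the 15 of 35 named calls that were tested and passed under each alternative and without each library. IL7R was removed by the filter with the 30000 strongest peaks. STXBP6, BMP7 and TP63 did not pass with the 30000 strongest peaks (adjusted p = 0.081, 0.112 and 0.458).

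**Figure D2:**
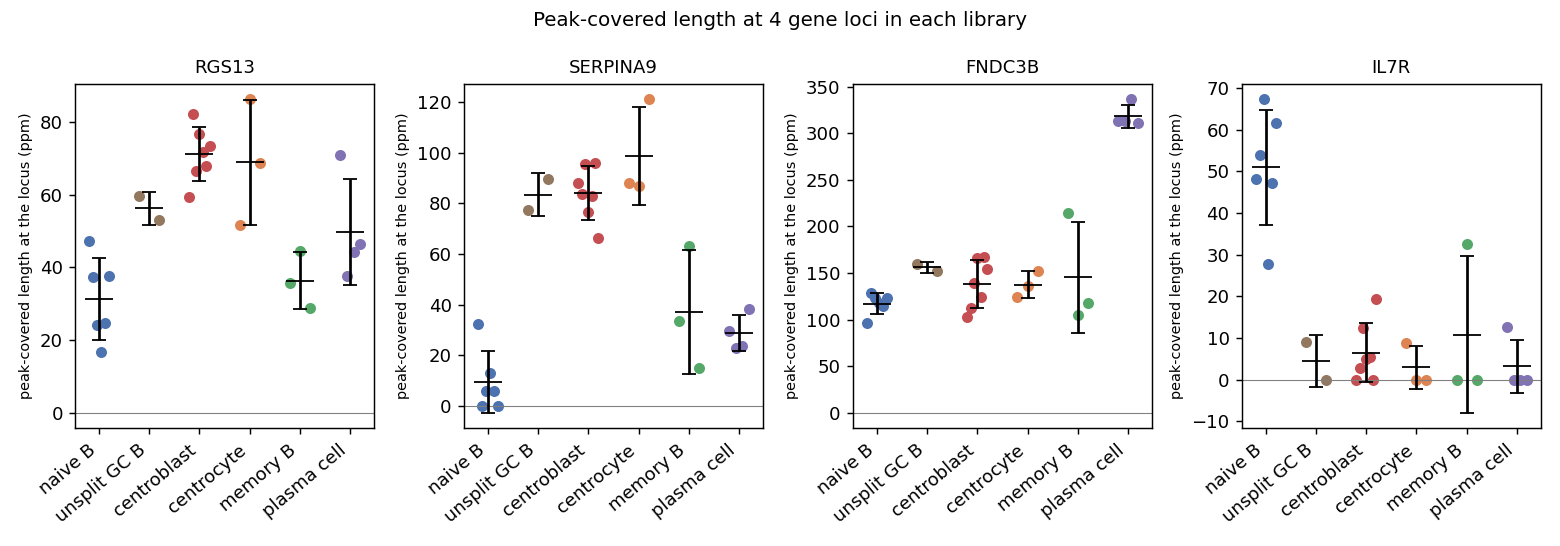
Peak-covered length in ppm of each library's total at 4 loci, with each point a library and the bars the mean and SD of its group. RGS13 and SERPINA9 are highest on average in the germinal centre groups, FNDC3B lies between 311 and 336 ppm in the 4 plasma cell libraries, and IL7R averages 51.0 ppm in naive B cells and 6.44 ppm in centroblasts.

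Unsplit germinal centre B cells (n = 2) were set against naive B cells (n = 6) as a comparison without the CXCR4 gate. SERPINA9 rose by 2.98 ± 0.49 (adjusted p = 0.00159) and SUGCT, another germinal centre gene, by 1.37 ± 0.32 (adjusted p = 0.0172). KLF2, a quiescence and trafficking factor, fell by 1.09 ± 0.19 (adjusted p = 0.00307). GBP2 and RNASE1 were listed at 0 in both unsplit libraries. Among markers of other cell types the T cell gene ICOS rose by 2.27 ± 0.61 (adjusted p = 0.0408) and IL7R fell by 2.70 ± 0.70 (adjusted p = 0.0337). The natural killer cell gene NCAM1 stood at 2.20 ± 0.71 (adjusted p = 0.0934) and TP63 at 1.60 ± 0.54 (adjusted p = 0.115). In all 549 loci passed, 372 higher and 177 lower. The split was 621 and 641 with the 30000 strongest peaks, 395 and 493 with only these 2 groups in the fit and 26 and 37 without unsplit replicate 2. CADPS, STXBP6, SCNN1B and CADM1 were again among the 8 with the largest rises. The count was 48 without unsplit replicate 1, 63 without unsplit replicate 2 and 902 without naive B cell replicate 4, and 58 within the 1 name style both groups share.

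Centrocytes were compared with centroblasts to see which loci follow the CXCR4 gate within the germinal centre. No locus of 17711 passed in limma, and 774 had an unadjusted p below 0.05, fewer than 1 in 20. CXCR4 itself, on which these cells were separated, stood at 71.1 ± 51.3 ppm in centrocytes (SD, n = 3) and 100 ± 7.45 ppm in centroblasts (n = 7). Its log2 fold change was -0.87 ± 0.39 (95% confidence interval -1.67 to -0.06; adjusted p = 0.944). The germinal centre genes BCL6 (0.02 ± 0.26) and MME (0.03 ± 0.34) did not pass, and neither did the light zone marker CD83 (-0.22 ± 0.15). Among the lower loci the smallest unadjusted limma p lay at an uncharacterised gene (-1.17 ± 0.26; adjusted p = 0.944) that overlaps YBX3, a DNA and RNA binding protein gene (-1.36 ± 0.30; adjusted p = 0.944). Among the higher ones it lay at SIL1, a chaperone exchange factor gene (0.48 ± 0.13; adjusted p = 0.944). No member of any of the 12 lists passed over all genes or adjusted over the list alone by limma.

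The T cell list was higher in centrocytes as a whole (camera adjusted p = 0.0154; adjusted p = 0.935 with an estimated correlation; adjusted p = 0.0681 with an equal number of peaks per library), and its level relative to all genes was -0.298 ± 0.05 in centrocytes and -0.552 ± 0.279 in centroblasts (SD). That call was also lost without centroblast replicate 1 (adjusted p = 0.128), without centrocyte replicate 2 (adjusted p = 0.118) and without centrocyte replicate 3 (adjusted p = 0.0774). Adjusted p from camera was between 0.232 and 1 for the other 11 lists. By Fisher's exact test 0 of 52269 regions passed, 443 had an unadjusted p below 0.05, and none passed by limma on presence. The smallest p that 3 and 7 libraries allow is 0.00833, which did not pass the adjustment. In all 118 regions were present in each centrocyte and no centroblast library and 11 the reverse. With the 30000 strongest peaks 7 loci passed, and without centrocyte replicate 1, the centrocyte library with the least covered length, 2404 regions were separated, 2389 of them towards centrocytes. The separated count was 378 without centrocyte replicate 2, 407 without centrocyte replicate 3, 228 without centroblast replicate 2 and 203 without centroblast replicate 3. By its definition it cannot fall when a library is left out. The 95% intervals excluded a change of 1 on the log2 scale for 80.4% of the loci.

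Memory B cells were compared with naive B cells to see which loci differ between both resting populations. MME fell by 1.72 ± 0.35 (n = 3 against 6; adjusted p = 0.00893), from 129 ± 18.2 to 42.1 ± 32.5 ppm (SD). The germinal centre signalling gene GCSAM fell by 1.03 ± 0.21 (adjusted p = 0.00894), the proto-oncogene MYC by 0.96 ± 0.21 (adjusted p = 0.0132), the dark zone factor FOXO1 by 1.15 ± 0.30 (adjusted p = 0.0291) and BCL6 by 0.88 ± 0.26 (adjusted p = 0.0488). ITGAX, which encodes the integrin CD11c found on a subset of memory B cells, rose by 1.25 ± 0.37 (adjusted p = 0.0474). CD27, on which the cells were sorted, stood at 0.16 ± 0.20 (adjusted p = 0.683). These SE and p-values take their spread from all 6 groups and not from the libraries compared alone. FOXO1 stood at 139 ± 113 ppm in memory and 260 ± 44.1 ppm in naive B cells (SD). BCL6 stood at 42.9 ± 27.2 and 72.7 ± 6.07 ppm. With only these 2 groups in the fit 6 loci passed in place of 993.

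In all 993 loci passed, 295 higher and 698 lower; with median-ratio scaling in place of total covered length the split was 403 higher and 541 lower. It was 119 and 128 with the name style as a covariate, 64 and 62 without memory B cell replicate 1 and 45 and 32 without memory B cell replicate 3, so the excess of lower loci was not kept. Only 1 of the 33 named calls in memory B cells, at an uncharacterised locus, was kept under each alternative and without each library. Of 15 naive and resting B cell genes 0 rose and 4 fell, and 10 fell when adjusted over the list alone (camera adjusted p = 8.7e-05; adjusted p = 0.899 with an estimated correlation). They included the interleukin-4 receptor gene IL4R, by 0.82 ± 0.19 (adjusted p = 0.0172), and FCER2, which encodes CD23, by 0.70 ± 0.17 (adjusted p = 0.0208). The 20 B cell identity genes were lower as a list (camera adjusted p = 0.0025; adjusted p = 0.943 with an estimated correlation) with 0 and 0 members passing over all genes and 0 higher and 6 lower adjusted over the list alone, and PAX5, the B lineage commitment factor, stood at -0.84 ± 0.26 (adjusted p = 0.0582). That list call was lost without memory B cell replicate 1 (adjusted p = 0.131). Of 21 germinal centre genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), of 15 dark zone genes 0 rose and 1 fell (0 and 1), of 21 light zone and activation genes 0 rose and 2 fell (0 and 3), of 16 memory genes 1 rose and 0 fell (1 and 0), and of 22 plasma cell genes 0 rose and 2 fell (0 and 7). The last were CD38, against which the cells were gated, by 0.85 ± 0.18 (adjusted p = 0.0109) and the disulfide isomerase family gene TXNDC5 by 1.10 ± 0.23 (adjusted p = 0.0112). Markers of T cells moved with this comparison. ICOS rose by 2.58 ± 0.53 (adjusted p = 0.00932) and BCL11B by 2.32 ± 0.52 (adjusted p = 0.015), IL7R fell by 2.47 ± 0.61 (adjusted p = 0.023). The level of the T cell list relative to all genes was -0.199 ± 0.694 in memory B cells against -0.378 ± 0.159 in naive B cells (SD). The higher mean rests on memory B cell replicate 2, at 0.512, since replicates 1 and 3 stood at -0.876 and -0.233. Of 19 T cell genes 2 rose and 1 fell (2 and 3 adjusted over the list alone), of 8 natural killer cell genes 1 rose and 1 fell (2 and 1), of 11 epithelial and stromal genes 2 rose and 1 fell (2 and 2), and of 13 myeloid and 12 housekeeping genes none passed by limma, over all genes or over the list alone. Adjusted p from camera was between 0.121 and 0.916 for these and the other lists not called.

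By Fisher's exact test 0 of 38374 regions passed and 1648 had an unadjusted p below 0.05. The smallest p that 3 and 6 libraries allow is 0.0119, which did not pass the adjustment. Limma on presence called 530, as many as the separated regions, so it is not further evidence beyond them. The separated regions, present in each library of one group and in none of the other, were 78 memory-only and 452 naive-only. The split was 920 and 478 without memory B cell replicate 1 and 507 and 472 without memory B cell replicate 3. Naive-only regions were nearest to SLITRK5 7 times and to SLC24A2 6 times. The number of loci depended on single libraries. It was 77 without memory B cell replicate 3, 126 without memory B cell replicate 1, 3879 without memory B cell replicate 2, 422, 468, 494 and 519 without naive B cell replicates 6, 3, 5 and 2, and 1629 without naive B cell replicate 4. It was 247 with the name style as a covariate, 463 with the 30000 strongest peaks and 6 with only these 2 groups in the fit. It was 0 against only the 3 naive B cell libraries of the same name style, and also 0 against the 3 of the other style. Separated regions numbered 14485 without memory B cell replicate 2, 1398 without memory B cell replicate 1, 979 without memory B cell replicate 3 and 1125 without naive B cell replicate 4. A rise from 530 is built into leaving out a library, so only the differences between these counts are informative.

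**Figure D3:**
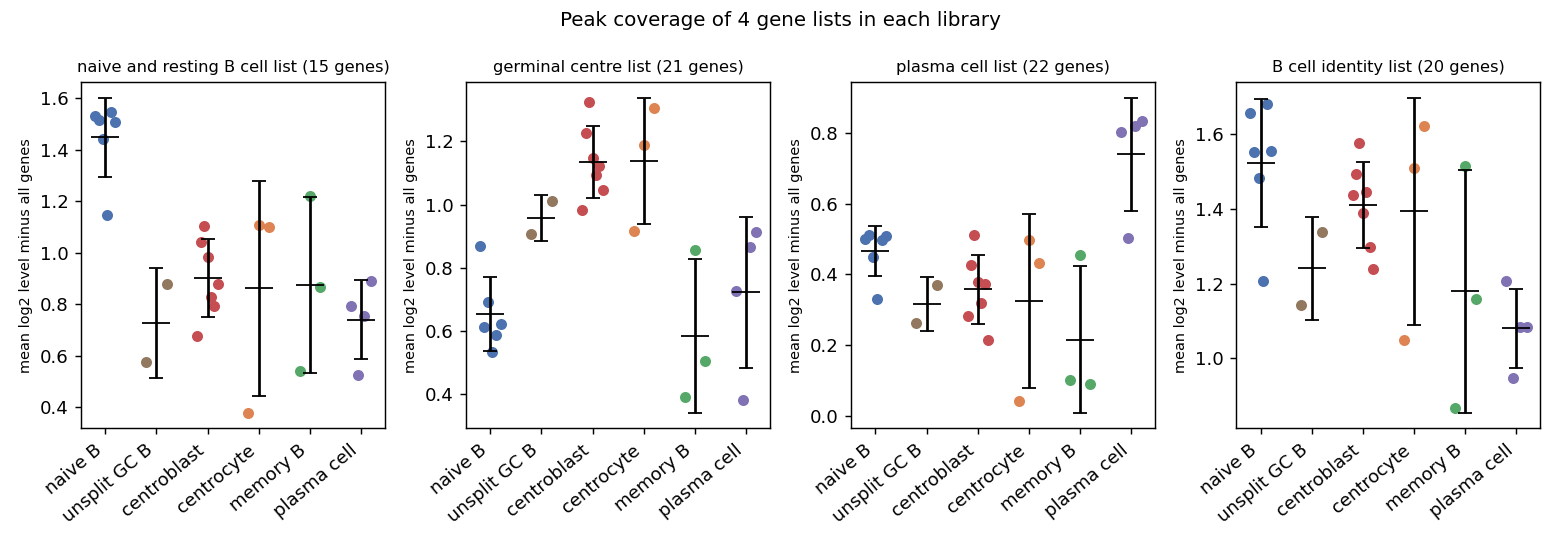
Mean log2 peak coverage of 4 gene lists minus that of all genes in each library, with each point a library and the bars the mean and SD of its group. The naive and resting list averages 1.448 in naive B cells and 0.740 in plasma cells, the germinal centre list 0.653 in naive B cells and 1.135 in centroblasts, and the plasma cell list 0.467 in naive B cells and 0.740 in plasma cells.

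Plasma cells were compared with naive B cells to see which loci differ at the antibody-secreting end of B cell differentiation. FNDC3B, a gene of the plasma cell list, rose from 117 ± 11.3 ppm (SD, n = 6) to 318 ± 12.1 ppm (n = 4), a log2 fold change of 1.41 ± 0.16 (SE; adjusted p = 5.86e-06). ELL2, the elongation factor that favours secreted immunoglobulin mRNA, rose by 0.78 ± 0.16 (adjusted p = 0.00195), and SDC1, which encodes the plasma cell marker CD138 and was named after its value was seen, rose by 1.72 ± 0.37 (adjusted p = 0.00277). CD74, the invariant chain of MHC class II, fell by 0.88 ± 0.14 (adjusted p = 0.000207) and SPIB, a B cell transcription factor, by 0.61 ± 0.15 (adjusted p = 0.00955). The lymphocyte egress receptor gene S1PR1 fell by 1.24 ± 0.26 (adjusted p = 0.00225) and IL4R by 0.77 ± 0.17 (adjusted p = 0.00365).

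In all 2698 loci passed, 1244 higher and 1454 lower. The split was 1188 and 1030 with the 30000 strongest peaks, 1338 and 1157 with the covered length as a covariate, 1828 and 1776 with flanks of 50 kb, and 210 and 121 within 1 of the name styles. Of 15 naive and resting B cell genes 0 rose and 9 fell, and 12 fell when adjusted over the list alone (camera adjusted p = 6.97e-06; adjusted p = 0.892 with an estimated correlation). Of 20 B cell identity genes 0 rose and 10 fell, with 1 and 11 adjusted over the list alone (camera adjusted p = 8.7e-05; adjusted p = 0.899 with an estimated correlation). PAX5 stood at -0.64 ± 0.24 and did not pass (adjusted p = 0.0718). Of 22 plasma cell genes 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0462; adjusted p = 0.899 with an estimated correlation; adjusted p = 0.057 with an equal number of peaks per library). The gene that fell was IRF4, by 0.68 ± 0.21 (adjusted p = 0.0343), and the plasma cell regulators PRDM1 and XBP1 stood at 0.33 ± 0.18 (adjusted p = 0.217) and 0.49 ± 0.23 (adjusted p = 0.169). The plasma cell list call was also lost without naive B cell replicate 1 or 4 (adjusted p = 0.0531 and 0.0948) and without plasma cell replicate 1, 3 or 4 (adjusted p = 0.118, 0.077 and 0.15). Of 21 germinal centre genes 4 rose and 1 fell (5 and 4 adjusted over the list alone), among them SERPINA9, by 1.57 ± 0.39 (adjusted p = 0.00803), and the falling LMO2, by 1.56 ± 0.44 (adjusted p = 0.0182). Of 15 dark zone genes 1 rose and 1 fell (1 and 1), of 21 light zone and activation genes 0 rose and 3 fell (0 and 3), and of 16 memory genes 2 rose and 0 fell (3 and 2), AIM2 by 0.43 ± 0.13 (adjusted p = 0.0264) and the Fc receptor-like gene FCRL5 by 1.21 ± 0.39 (adjusted p = 0.0373).

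The largest rises were at STXBP6 (3.79 ± 0.45), SCNN1B (3.45 ± 0.30), THSD4 (3.35 ± 0.39), the tight junction gene TJP1 (3.31 ± 0.42) and CADM1 (3.31 ± 0.31), and the largest falls at ZBTB16, a zinc finger repressor gene (-3.23 ± 0.49), and ARPP21 (-3.21 ± 0.52). Markers of other cell types moved here too. TP63 rose by 2.87 ± 0.43 (adjusted p = 0.0001) and CDH1, which encodes E-cadherin, by 1.51 ± 0.18 (adjusted p = 1.27e-05), 2 of 11 epithelial and stromal genes that rose against 1 that fell (2 and 1 adjusted over the list alone). Of 19 T cell genes 1 rose and 4 fell (1 and 7), among them IL7R, by 2.99 ± 0.56 (adjusted p = 0.000869), and the kinase gene ZAP70, by 1.32 ± 0.27 (adjusted p = 0.00221). Of 8 natural killer cell genes 1 rose and 1 fell (1 and 1) and of 13 myeloid genes 1 rose and 0 fell (0 and 0). Of 12 housekeeping genes 0 rose and 1 fell (0 and 1), ACTB, by 0.67 ± 0.16 (adjusted p = 0.00782), which stood at 0.55 without flanks. Adjusted p from camera was between 0.121 and 0.916 for the 9 lists not called.

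Fisher's exact test passed for 5866 of 28176 regions, 1312 present in all 4 plasma cell and in 0 of 6 naive B cell libraries and 4554 the reverse. Chance gives such a region an exact p of 0.00476, the smallest these libraries allow. PRDM1, which encodes the plasma cell repressor Blimp-1, was the nearest coding gene to 7 plasma-only regions, one of them inside the gene at chromosome 6, 106101962 to 106102369, and to 2 naive-only regions, one inside the gene at 106103621 to 106104134. XBP1 was nearest to 1 plasma-only region, at chromosome 22, 28819247 to 28819809. Naive-only regions were nearest to CD83 8 times, to CXCR4 6 times and to PAX5 3 times, 2 of these inside PAX5 at chromosome 9, 37002408 to 37002774 and 37032763 to 37033217. Regions nearest to plasma cell genes lay 22 times towards plasma cells and 9 times towards naive B cells (Fisher's exact adjusted p = 2.46e-07 against 22.4% of all separated regions lying towards plasma cells), and those nearest to naive and resting genes 3 and 51 times (Fisher's exact adjusted p = 0.0179), in a test added after the counts were seen. Regions near a gene are not independent of each other, so these p-values do not describe separate genes. FNDC3B, a gene of the plasma cell list, was alone nearest to 6 of the plasma-only regions.

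Both groups held both styles of sample name, 2 plasma cell and 3 naive B cell libraries in each, and 1612 and 331 loci passed within them. The region count was 0 when any 1 of the 4 plasma cell libraries was left out, where 3 and 6 libraries allow no p below 0.0119, and 9245 without naive B cell replicate 4. Of 38 named loci that passed, 11 were tested and passed under each alternative and without each library, among them FNDC3B, SCNN1B, STXBP6, CADM1, CDH1 and ZBTB16. With the 30000 strongest peaks TJP1 was removed by the filter and THSD4 stood at 1.85 ± 0.70 and did not pass (adjusted p = 0.0849).

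**Figure D4:**
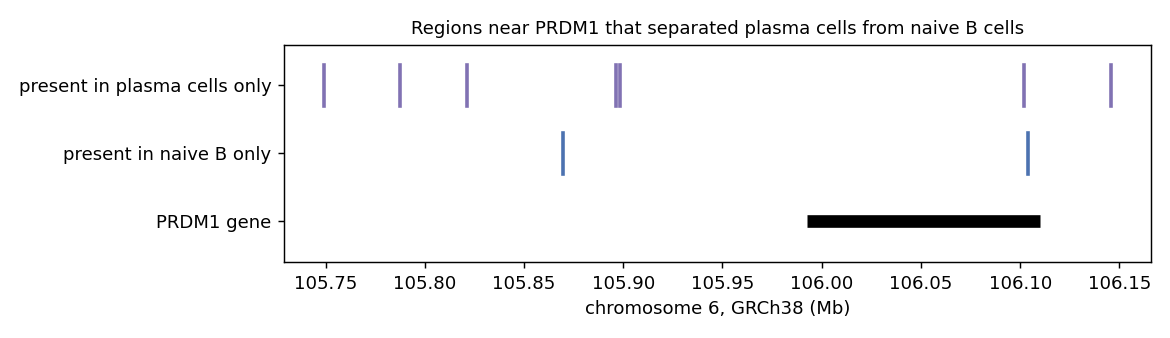
Regions near PRDM1 on chromosome 6 (GRCh38, position in Mb) that were present in every plasma cell library and no naive B cell library, or the reverse, with the gene drawn as a black bar. Of the 9 regions, 7 were found in plasma cells and 2 in naive B cells, and 1 of each lies within the gene.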

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

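The counts of other splits of the libraries, the count without memory B cell replicate 2, the count of epithelial genes called higher and the count of leading loci that lost their call were chosen after the result was seen; the other tests of this part were set before their values were seen.

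For centroblasts against naive B cells, 1 of 100 splits of the 13 libraries gave as many changed loci as the real one, namely the real one itself with 2207, and the highest other split gave 198. For regions 1 of 100 gave as many, the real one with 5080, and the highest other split gave 0. A small number of separated regions cannot pass the adjustment, so this 0 overstates the contrast. By separated regions the real split, with 2094, was again the only 1 of 100 as large, and the highest other gave 149. For plasma cells against naive B cells 1 of 100 splits gave as many loci, the real one with 2698, and the highest other gave 544. For regions 1 of 100 gave as many, the real one with 5866, and the highest other gave 0, but 1036 by separated regions, where the real split gave 5866. Chance assignment of libraries to groups can be excluded for these 4 counts at a share of 0.05, if the libraries are treated as exchangeable.

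The first pattern is the count of 993 changed loci between memory and naive B cells. Of 84 splits, the real one included, 2 gave as many loci. For the 530 separated regions chance cannot be excluded, with 8 of 84 as large. For the loci the rank cannot decide on chance, since the structure described next means that the libraries cannot be treated as exchangeable. With only these 2 groups in the fit 6 loci passed. Against 3 naive B cell libraries of the same name style 0 passed, and 0 also against the 3 of the other style. That 0 is thus no sign of the name style. The highest other splits gave 4852 loci and 6952 regions, several times the real counts. Both part memory B cell replicates 1 and 3 and naive B cell replicate 4 from the other 6, so these 9 libraries hold a structure other than the cell type. These 3 had the highest first principal component of the 9 (74.2, 59.9 and 36.7), but naive B cell replicate 4 covered 30.4 Mb, near replicates 5 and 2 (30.8 and 31.1 Mb, at -28.3 and -13.6 on that component), so the structure was not shown to be the covered length. Whether the amount called sets how many loci pass cannot be told apart. Without memory B cell replicate 2, which had the most peaks and covered length of the memory B cell libraries, 3879 passed. The count also moved without memory B cell replicate 1 (126) or 3 (77). Replicate 2 lay apart from both on the first component (-45.3), so leaving it out can narrow the spread whatever set it apart. Whether the amount called sets the direction of the changes cannot be told apart either. Of 3328 loci called without memory B cell replicate 2 and naive B cell replicate 1, 73.11% had the same sign between these held-out libraries. The shares were 67.38% of the 886 higher and 75.18% of the 2442 lower ones, where 56.93% of all loci lay below 0. The 73.11% is past the 60% written before and argues against the amount called. That bound rests on 1 library of each cell type, too few to exclude the amount called. The excess of lower loci was also lost without memory B cell replicate 1 or 3. The difference between both cell types stays open as a hypothesis, as does the style of the sample names, under which 247 loci passed as a covariate.

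The second pattern is that STXBP6, SCNN1B, THSD4 and CADM1 were among the 8 loci with the largest rises both in centroblasts and in plasma cells, although these genes are on none of the 12 lists. Both rankings use the same 6 naive B cell libraries, in which these loci averaged 2.97, 3.57, 12.5 and 15.4 ppm, so they are not independent. Whether epithelial cells in the sort account for it cannot be told apart, although the CD20 gate was meant to exclude them: of 6 epithelial genes of the list 3 were called higher in centroblasts (all 6 fold changes above 0, from 0.53 to 2.37) and 2 in plasma cells (4 above 0, from -0.17 to 2.87), below the 3.03 to 4.12 and 3.01 to 3.79 of the 8 leading loci, while CDH1 and TP63 stood at 71.9 and 57.3 ppm in centroblasts, 136 and 85.9 ppm in plasma cells and 45.1 and 10.1 ppm in naive B cells. Weakly called peaks do not account for 6 of the 8 leading loci in centroblasts, which passed with the 30000 strongest peaks of each library; for the other 2 it cannot be told apart, since STXBP6, the largest rise, went from 4.12 ± 0.39 to 2.48 ± 0.91 (SE; adjusted p = 0.081) and BMP7 from 3.23 ± 0.40 to 1.69 ± 0.67 (adjusted p = 0.112), with smaller folds and wider spread. In plasma cells 3 of 7 loci tested passed, between the bounds of 2 and 6 written before, so this cannot be told apart there either. That these loci open in both cell types stays open as a hypothesis.

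The third pattern is that no locus passed between centrocytes and centroblasts in limma. A real count of 0 is met by all 100 of 100 splits whatever the data, so this count says nothing about chance (highest other 4). For the 129 separated regions chance cannot be excluded, since 28 of 100 splits gave as many, and the highest other, 1913, parts centrocyte replicate 2 and centroblast replicates 2 and 3, the 3 libraries of the 10 with the most covered length (58.4, 55.4 and 54.0 Mb), a structure of the samples that goes with the amount called. In their sample names 4 centroblast libraries carry GCB, as the unsplit cells do, although the series design text uses it for CXCR4+ centroblasts. Whether these 4 libraries account for the lack of passing loci cannot be told apart. With the 3 others alone 0 loci passed in limma, within the bound of 5 written before, and 414 regions were separated, a count that cannot fall with fewer libraries. A group of 3 also has less power, with 934 in place of 2207 loci against naive B cells. The 95% intervals excluded a 2-fold change for 80.37% of loci, which just passes the bound of 80% written before, but for 71.23% to 80.27% without 1 library, a range looked at afterwards, so whether the spread between libraries hides such changes was left as cannot be told apart.

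Of 258 groups of values examined, 26 held a library far from the others, where chance gives about 1 in 20 groups, or 12.9, and 11 of the 26 concern naive B cell replicate 4. In naive B cell replicate 1 the covered length was 46.9 Mb (30.4 to 35.1 Mb in the other 5). In naive B cell replicate 4 the level of the naive and resting list was 1.15 (1.44 to 1.55 in the others), that of the light zone list 0.742 (0.961 to 1.09) and that of the plasma cell list 0.33 (0.451 to 0.512). In the same library CD27 stood at 32.2 ppm (54.7 to 65.2), CCR7 at 54.0 ppm (81.0 to 91.6), FCER2 at 78.9 ppm (90.3 to 94.0), ZBTB16 at 204 ppm (317 to 375), CADM1 at 36.4 ppm (4.27 to 16.1), NCAM1 at 53.9 ppm (0 to 14.6), and BMP7 and TJP1 at 17.9 and 10.7 ppm where the others were listed at 0. In centroblast replicate 1 the level of the T cell list was -1.11 (-0.612 to -0.265 in the other 6), THSD4 stood at 97.6 ppm (144 to 177) and SIL1 at 48.4 ppm (58.5 to 63.8). In centroblast replicate 3 TP63 stood at 85.1 ppm (42.5 to 60.1), and in centroblast replicate 5 MKI67 at 23.3 ppm (42.7 to 54.3). In centroblast replicate 7 SLC24A2 stood at 124 ppm (8.77 to 43.7), NETO1 at 52.6 ppm (0 to 13.0) and BCL11B at 76.0 ppm (6.04 to 28.4). In plasma cell replicate 2 the level of the plasma cell list was 0.502 (0.804 to 0.833 in the other 3) and MKI67 stood at 18.5 ppm (39.0 to 40.9). In plasma cell replicate 1 IL7R stood at 12.7 ppm where the others were listed at 0, and BCL11B at 6.99 ppm (20.4 to 22.3). In plasma cell replicate 3 SCNN1B stood at 57.4 ppm (78.6 to 82.8) and FNDC3B at 336 ppm (311 to 313).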

How the results depend on the processing

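Of 406 counts and p-values recomputed under alternatives for 25 results, 58 were weaker, 36 stronger and 312 neither, which for a list or peak number means that whether its p passed did not change and for a count of calls that it stayed within 1.5 times. Of the 312, 30 are Fisher counts of 0 for centrocytes and memory B cells, where the smallest p that the libraries allow did not pass the adjustment. Another 39 are peak numbers, whose size moved and, in plasma cells, whose sign turned. Neither kind shows stability. The stronger ones include separated regions with fewer libraries, a count that cannot fall by its definition. Among named genes and lists 4 values turned their direction and passed before or after, S1PR2, ACTB and AURKA in plasma cells (-0.05, -0.67 and 0.58 before) and the memory list in centrocytes (0.529 before), and the cause of these changes was not tested. Values that turned without passing on either side, several lists among them, are not counted here. The gene bodies with no flanks or with 50 kb, the equal number of peaks with the covered length as covariate, the lists with the covered length or without 1 library, the peak numbers without 1 library, the fits without the most deeply called shared name code or with only the centroblasts named CB, and memory B cells against naive B cells of the same name style were chosen after seeing the data. Of the genes named, 15 of 35 called were tested and called under all alternatives in centroblasts, 1 of 33 in memory B cells, 11 of 38 in plasma cells and 0 of 22 in unsplit cells. Windows around transcription start sites, motif content and a regression on GC content were not run.

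With the replicate number as a block, limma called 2150 loci in centroblasts, 260 in memory B cells, 1913 in plasma cells and 380 in unsplit cells against naive B cells, and 0 for centrocytes against centroblasts. The numbers do not pair the libraries: the median correlation of libraries with the same number was 0.004, with 14 of 45 pairs above 0.1. Libraries that share a name code had a median of 0.501, and -0.023 once the covered length was removed.

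The 30000 strongest peaks gave 7 loci for centrocytes against centroblasts, 463 in memory B cells and 1262 in unsplit cells, 202 separated regions for centrocytes and 960 in memory B cells, and 0.99 for S1PR2 in plasma cells. An equal number of peaks gave 1125 separated regions in memory B cells and adjusted p-values of 0.0681 for the T cell list in centrocytes and 0.057 for the plasma cell list in plasma cells. The covered length as covariate gave 1152 loci in unsplit cells, 0.191 for the T cell list and 0.0449 for the memory list, lower in centrocytes, and with an equal number of peaks 3439 in centroblasts, 2 in centrocytes and 1250 in unsplit cells. The name style as covariate gave 247 loci in memory B cells and 284 in unsplit cells. Fits of only the 2 groups gave 3318, 6 and 888 loci in centroblasts, memory B cells and unsplit cells. Gene bodies without flanks gave 365 loci in unsplit cells and 0.55 for ACTB in plasma cells, and those with 50 kb gave 3383 in centroblasts, 917 in unsplit cells and -0.07 for AURKA in plasma cells. Without the 4 libraries of the most deeply called name code 3046 loci passed in memory B cells, and with only the centroblasts named CB 934 in centroblasts and 414 separated regions for centrocytes. Within one name style 1027 loci passed in centroblasts, 1612 and 331 in plasma cells and 58 in unsplit cells. In memory B cells 0 passed against naive B cells of the same style, and also 0 against those of the other style. Without the filter on margins Fisher's test called 0 regions in centroblasts and 0 in plasma cells, and limma on presence called 530 in memory B cells and 10677 in plasma cells.

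Under an estimated correlation the lists stood at 0.892 (naive and resting, centroblasts), 0.892 (germinal centre, centroblasts), 0.935 (T cell, centrocytes), 0.899 (naive and resting, memory B cells), 0.943 (B cell identity, memory B cells), 0.892 (naive and resting, plasma cells), 0.899 (plasma cell, plasma cells) and 0.899 (B cell identity, plasma cells). Under the other alternatives the same lists ranged over 7.66e-08 to 0.000125, 6.13e-05 to 0.00206, 0.00499 to 0.191, 1.59e-05 to 0.00224, 0.000464 to 0.131, 2.09e-06 to 6.08e-05, 0.00206 to 0.15 and 3.29e-05 to 0.00206.

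Without each library in turn the changed loci ranged from 77 to 3879 in memory B cells and 48 to 902 in unsplit cells, and the changed regions from 2172 to 3696 in centroblasts and 0 to 9245 in plasma cells. Separated regions ranged from 2172 to 3696 in centroblasts, 147 to 2404 in centrocytes, 559 to 14485 in memory B cells and 5971 to 9245 in plasma cells. With all libraries they were 2094, 129, 530 and 5866. The count cannot fall when a library is left out, so the rise itself does not show dependence on single libraries. The lists ranged from 0.000464 to 0.131 (B cell identity, memory B cells), 0.00597 to 0.15 (plasma cell, plasma cells) and 0.00499 to 0.128 (T cell, centrocytes), and the memory list in centrocytes from 0.0418 to 0.774, at 0.0418 higher without centrocyte replicate 1 and 0.0418 lower without centrocyte replicate 2. The difference in peak number ranged from 9942 to 16936 for centroblasts, 10045 to 17539 for centrocytes, 3478 to 11144 for memory B cells and -6067 to 5446 for plasma cells (8432 and 306 with all libraries).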

Other observations

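The tests of this part were set before their values were seen; the interval next to BCL6 was chosen because regions that separate centroblasts from naive B cells lay in it, so its p-value comes from the libraries that led to the choice and restates that observation.

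Centroblasts, centrocytes, plasma cells and memory B cells were compared with different naive B cell libraries, 3 for each, so that the comparisons share no library. Naive B cell replicates 1 to 3 carry the name style of the centroblasts and replicates 4 to 6 the other style. With the replicates exchanged, centroblasts were thus set against naive B cells of another name style only. Libraries of different groups can also share a name code (10 such pairs), so the comparisons may not be independent. Of 2140 loci called in centroblasts against naive B cell replicates 1 to 3, 87.15% had the same sign in plasma cells against replicates 4 to 6, and 82.06% of 1761 loci with the replicates exchanged. Loci called higher in both numbered 143, where independent lists would share 21.6, and those lower in both 95, where they would share 9.4; 3 went opposite ways. With the replicates exchanged the counts were 214 (46.5), 183 (24.9) and 4. In centrocytes 97.1% and 96.54% of the centroblast loci had the same sign, above the bound of 75% written before, as in plasma cells. In memory B cells the shares were 84.39% and 74.11%, and since the lower one falls under that bound whether their differences fall at the same loci cannot be told apart. The correlation across genes, which are not independent replicates, was 0.554 and 0.427 for plasma cells and 0.722 and 0.714 for centrocytes. These values are consistent with a set of loci that differ between naive B cells and cells of the germinal centre and plasma cells alike, a hypothesis that does not exclude a property of the naive B cell sort as a whole.

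The gap between BCL6 and its neighbour LPP, a stretch of 407.6 kb without coding genes on chromosome 3 (187745469 to 188153020; non-coding genes in it were not examined), held 597.6 ± 70.5 ppm of the peak-covered length in centroblasts (SD, n = 7) and 421.2 ± 56.8 ppm in naive B cells (n = 6), an exact permutation p of 0.00233 and 0.0117 when adjusted over 5 groups. It held 594.4 ± 122 ppm in centrocytes (n = 3; exact permutation p = 0.0952), 518.5 ± 34.5 ppm in the unsplit cells (n = 2; exact permutation p = 0.0714), 297.5 ± 150 ppm in memory B cells (n = 3; exact permutation p = 0.119) and 312.7 ± 130 ppm in plasma cells (n = 4; exact permutation p = 0.133), none of which passed. The number of peaks in it was 44 to 78 in the centroblast and 32 to 46 in the naive B cell libraries. The BCL6 locus itself stood at 0.18 ± 0.21 in centroblasts and did not pass as a whole, although 1 region 461 bp from the gene was present in all 7 centroblast and in 0 of 6 naive B cell libraries. That this gap holds distal elements of BCL6 that open in the germinal centre is a hypothesis that was not tested here, and LPP is an equal possibility.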
